A study of Mus musculus with 4 samples.

How the data were processed

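RNA from fibroblast preparations of mouse back-skin dermis was isolated with a column kit and made into Illumina libraries, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Tables of read counts per gene were deposited by the authors for each library, with columns for total and unique reads in exons, introns and whole genes, per the file headers. The deposited tables also give TPM and RPKM computed by the authors, which were used to examine what the files hold and enter no test. The deposited comparison gives log2 fold changes, p-values and false discovery rates by the authors, with a larger group mean in RPKM that was not used, and 4215 of its 25644 rows hold an error text in place of a test. The genome build is GRCm38, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the model behind the authors' deposited comparison are not given in the sources used here. Of the gene identifiers in the files, 25627 are in GENCODE M21 and 99.6% of these have identical coordinates there. Transcript tables were not used here. Libraries were joined by gene identifier, because the name cell of Il1b was blank in 1 table.

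Total exon reads per gene, which equal the expression value column in every row, were the counts tested. They summed to between 129448725 and 145737260 per library. Intron reads made up 9.78% to 11.6% of gene reads. No pair of libraries agreed within sampling noise, since the chi-square per gene was at least 209 in each pair. In edgeR 4.0.16 genes were filtered with filterByExpr, libraries were scaled by TMM, dispersions were estimated with estimateDisp and the groups were compared with the robust quasi-likelihood F-test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error was taken as the absolute log2 difference divided by the square root of F. The common biological coefficient of variation was 0.327. A rank or permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so none was used. The median log2 difference of all genes was 0.015 with TMM and 0.137 with library size only, a shift of 0.122. Counting error alone is small at this depth, and the ratio intervals given for genes with 3 reads or fewer in a group are exact 95% binomial intervals that cover counting error only.

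Before the data were examined, 35 gene lists (18 of responses, the others of cell types and RNA quality) were fixed from general knowledge. Of their 689 symbols 679 were in the files. Lists with at least 5 tested genes were compared with other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 35 lists. Camera with an estimated correlation called 0 of the 35 lists, and none of the 25 list calls held with it. Among those 25 the estimated correlation ranged from -0.03 (p53 targets) to 0.99 (MHC class II). Their unadjusted p by that test ranged from 0.0487 (erythrocyte markers) to 0.542 (T and NK cell markers). Adjustment over the lists brought these to between 0.70 and 0.73, so the shared adjusted value hides differences between lists. Fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes. List medians per library used log2(CPM + 0.02).

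The genes named were chosen by a rule fixed in the same way: Il1b, Il1a, Nlrp3, Casp1, Cdkn1a and Mdm2; up to 10 genes per direction with the largest log2 difference among those past the threshold, with a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes and pseudogenes, or those with the smallest p where none passed; and the 4 genes of each response list and 3 of each other list with the smallest p. No lower gene passed, so the smallest p was used in that direction. Values of some genes that this rule names are not reported here. Of 142 named genes 26 overlap another counted gene, and without a known strand setting reads of such pairs cannot be separated. Among these are Alas2 with Apex2, Irf8 with Gm20388, H2-DMa with Brd2 and Rps28 with Kank3.

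The scripts were tested on counts simulated from these libraries with the estimated dispersion. This comparison was simulated over 16852 genes. The quasi-likelihood test recovered 16 of 67 genes changed 2-fold, 66 of 67 changed 4-fold and 66 of 66 changed 16-fold. It made 4 calls among 16652 unchanged genes. On the same simulated counts DESeq2 recovered 22, 67 and 66 genes of these classes, with 57 calls among the unchanged genes. The edgeR likelihood ratio test recovered 21, 66 and 66, with 9 such calls. DESeq2 thus made more false calls than either edgeR test, which limits the DESeq2 counts given below. A planted list of 20 genes was recovered with 0 of the other 35 lists called. These simulations used a dispersion trend and not the spread of each gene. They also drew each gene independently, so simulated lists held no correlation between genes. In the data the estimated correlation of the called lists ranged from -0.03 (p53 targets) to 0.99 (MHC class II). The simulated list result therefore cannot show how often lists of correlated genes are called falsely. Alternatives fixed beforehand were size factors by RLE, upper quartile and library size only, the low-count filter, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, a replicate block, unique exon reads, other thresholds, other list tests and leaving out each library. Exon plus intron reads, edgeR's legacy quasi-likelihood method and removal of a trend on exon length were added after seeing the data. The replicate numbers are not said to pair libraries, so no block was used in the comparison reported. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, checks and figures.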

Results

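RNA-seq was performed on dermal fibroblast preparations from the back skin of adult mice of the inbred strain C3H, taken 4 days after injection into the dermis of vehicle or of cisplatin, a platinum drug that crosslinks DNA. The vehicle and cisplatin groups held 2 libraries each. The labels do not say whether libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Exon reads assigned to 25644 genes summed to 129448725 and 134057035 in vehicle libraries 1 and 2, and to 145737260 and 130712473 in cisplatin libraries 1 and 2. A count of 3 reads corresponded to between 0.0201 and 0.0253 normalised counts per 1000000 (CPM). The single comparison of the design was cisplatin against vehicle, and because the series title names fibroblast IL-1β, the Il1b gene is given first. Values below are normalised read counts in CPM per library and log2 differences of cisplatin over vehicle with their standard errors (± SE, n = 2 libraries per group), positive where cisplatin was higher.

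The libraries of the cisplatin group lay further apart than those of the vehicle group. The SD over genes of the log2 difference between replicates was 0.896 for cisplatin and 0.546 for vehicle. The first principal component held 77.4% of the variance and placed the vehicle libraries at -87.5 and -52.1, cisplatin library 1 at 30.6 and cisplatin library 2 at 109. Of 17054 genes tested, 31.2% were higher in both cisplatin libraries than in both vehicle libraries and 30.0% were lower in both. A random order of 4 libraries gives 16.7% in each direction on average. Genes vary together, so a share above that value is not a test of the group difference. Of 22 gene lists that were higher as sets, 21 had a higher median in cisplatin library 2 than in library 1.

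Il1b, which encodes the inflammatory cytokine IL-1β, was at 0.876 and 1.31 CPM in the vehicle libraries and at 7.34 and 72.1 CPM in the cisplatin libraries. Its log2 difference was 5.18 ± 1.24, which did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.193). The gene (ENSMUSG00000027398) lies on the minus strand of chromosome 2, from 129364570 to 129371139 in GRCm38. Nlrp3, the sensor of the inflammasome that activates caspase-1, was at 0.497 and 0.589 CPM in vehicle and at 4.86 and 29.6 CPM in cisplatin, a log2 difference of 4.98 ± 1.04 (adjusted p = 0.181). Il1a, which encodes the related cytokine IL-1α, differed by 2.36 ± 0.63, and Casp1, the caspase that processes IL-1β, by 0.38 ± 0.24; neither passed. Among 23 measured genes of the inflammasome and IL-1 family list, 0 passed over all genes, while 11 higher genes and 0 lower genes passed adjusted over the list alone. At an unadjusted p under 0.05, 12 of the 23 were higher and 1 was lower, and DESeq2 called 12 higher and 1 lower. The members with the smallest p were Nek7 (0.69 ± 0.13), Casp4 (2.87 ± 0.58), the decoy receptor Il1r2 (2.78 ± 0.57) and the signalling receptor Il1r1 (0.63 ± 0.13). The list median was 1.94, and the list was higher as a set by camera (adjusted p = 1.35e-05), with adjusted p = 0.70 with an estimated correlation. Markers of macrophages and monocytes had a median log2 difference of 3.83 and neutrophil markers one of 2.80 in the same libraries. The Il1b call depended on the tool. Its adjusted p was 6.28e-07 by DESeq2 and 0.000359 by the edgeR likelihood ratio test. By limma-voom Il1b did not pass (4.39, adjusted p = 0.317). The log2 difference of Il1b also depended on single libraries. It was 6.03 without cisplatin library 1, 2.75 without cisplatin library 2, 4.93 without vehicle library 1 and 5.50 without vehicle library 2. A fit without 1 library leaves 1 in that group and takes the spread from the other group, here and in the results below.

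**Figure D1:**
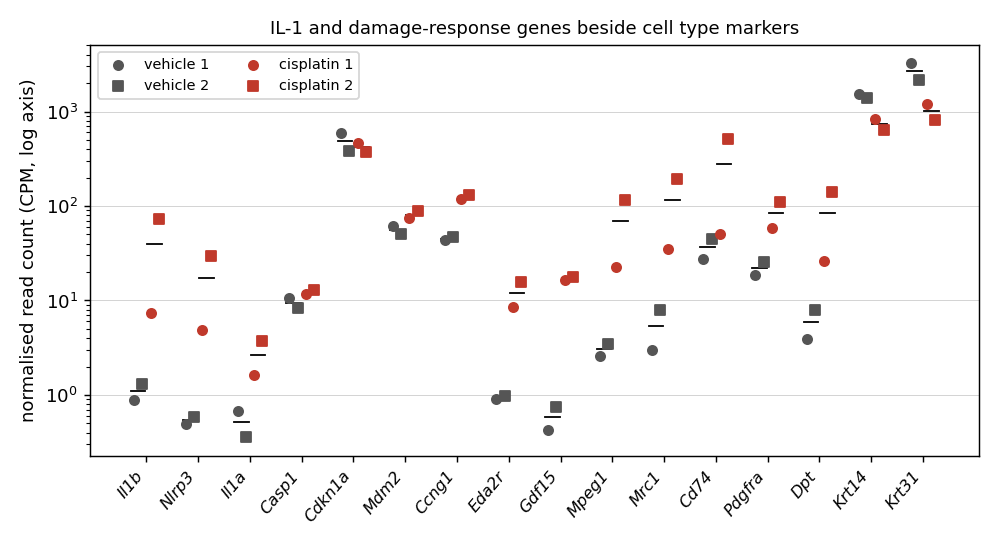
Normalised read count (CPM, log axis) of 16 genes in each of the 4 libraries, with vehicle in grey, cisplatin in red, replicate 1 as circles, replicate 2 as squares and a bar at each group mean. Il1b reached 7.34 and 72.1 CPM in the cisplatin libraries against 0.876 and 1.31 CPM in vehicle, and the macrophage genes Mpeg1 and Mrc1 were likewise higher in cisplatin library 2 than in library 1.

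After cisplatin 14 genes rose and 0 fell at an adjusted p of 0.05. Several of the 14 are genes of fat cells: Adipoq, which encodes the hormone adiponectin, rose from 0.286 and 0.231 CPM to 218 and 101 CPM (9.27 ± 0.58), Car3, a carbonic anhydrase abundant in fat, rose from 3.73 and 2.12 to 1273 and 785 CPM (8.46 ± 0.53), and Plin4, a lipid droplet protein, rose by 6.29 ± 0.41. Cyp2e1, a cytochrome P450 enzyme, had the largest difference of the 14, from 0.0842 and 0.209 CPM to 549 and 279 CPM (11.43 ± 0.67). Abcd2, a peroxisomal transporter, rose by 4.90 ± 0.23 and the amino acid transporter Slc1a5 by 3.35 ± 0.21. Cxcl13, a chemokine that attracts B cells, rose by 7.29 ± 0.45, and the complement gene C4b rose by 3.33 ± 0.15. Chil3, a chitinase-like gene of alternatively activated macrophages, rose by 8.55 ± 0.55 from 4 reads over both vehicle libraries to 1808 over both cisplatin libraries. Mup22, one of the major urinary protein genes, rose by 7.95 ± 0.47, but 0.4% of its exon reads were unique to it, so its value cannot be separated from other genes of that family. Fmo2 (2.78 ± 0.17) and Il6ra (3.13 ± 0.21) were also among the 14 and were named after their values were seen. All 14 adjusted p-values lay between 0.0404 and 0.0459 by edgeR's quasi-likelihood test. Of the 14 genes 4 were also called with library size only and 4 with upper quartile factors. The legacy version of that test called 0, with a smallest adjusted p of 0.0504. Unadjusted p-values under 0.05 were found for 2427 higher and 1121 lower genes. These counts were 2690 and 715 with library size only, 572 and 126 without vehicle library 1, 1040 and 541 without vehicle library 2, and 4360 and 2571 without cisplatin library 1. DESeq2 called 1744 genes higher and 394 lower, including the 14, whereas limma-voom called 0 in each direction, with 1865 higher and 1131 lower genes at an unadjusted p under 0.05. The count of higher genes was 0 without either vehicle library, 3304 without cisplatin library 1 and 764 without cisplatin library 2.

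**Figure D2:**
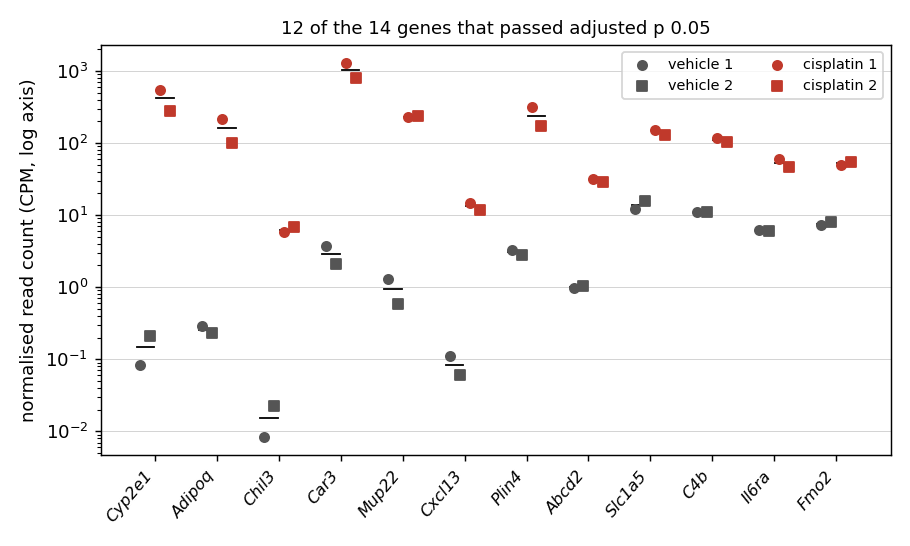
Normalised read count (CPM, log axis) in each library of 12 of the 14 genes that rose, ordered by log2 difference, with vehicle in grey, cisplatin in red and a bar at each group mean. The distance between groups ranges from 2.78 for Fmo2 to 11.43 for Cyp2e1 on the log2 scale. The replicates of each gene lie close together relative to that distance, which the test that chose these genes favours.

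No gene passed edgeR's quasi-likelihood test in the lower direction, where the smallest adjusted p was 0.0629, against 394 genes called by DESeq2 and 0 by limma-voom; without cisplatin library 1 the count was 973 and without cisplatin library 2 it was 35. At an unadjusted p under 0.05, 1121 genes were lower, with 715 by library size only, 126 and 541 without vehicle library 1 or 2 and 2571 without cisplatin library 1. The genes named here are therefore those with the smallest p among lower genes with a mean of at least 5 CPM and groups that do not overlap. Predicted genes and pseudogenes were left out of that ranking. Alas2, the erythroid enzyme of haem synthesis, was at 10.6 and 9.68 CPM in vehicle and at 1.61 and 1.61 CPM in cisplatin (-2.65 ± 0.28). Nrg2, a neuregulin growth factor, differed by -1.22 ± 0.15, Cdr2 by -1.21 ± 0.17, Tdh by -1.09 ± 0.17 and Phyhip by -1.14 ± 0.19. The metallothionein Mt4 differed by -1.68 ± 0.24. The mitochondrial respiratory genes Atp5e and Ndufa3 differed by -1.04 ± 0.14 and -1.06 ± 0.17, and the ribosomal protein genes Rps28 and Rpl38 by -1.02 ± 0.14 and -0.97 ± 0.14, with 65.9% of Rpl38 reads unique to it. With the trend on exon length removed, an alternative added after seeing the data, Rps28 was at -0.58, Rpl38 at -0.46, Atp5e at -0.45, Ndufa3 at -0.68 and Mt4 at -1.08.

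Genes that p53 is known to activate after DNA damage were higher as a set, by small amounts in most members. The median over 30 genes was 0.39 and 20 of them were higher in both cisplatin libraries than in both vehicle libraries. Over all genes 0 passed, 8 higher genes passed adjusted over the list alone, 10 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 9 higher. Ccng1 was at 43.6 and 46.7 CPM in vehicle and at 119 and 132 CPM in cisplatin (1.48 ± 0.15), with Dglucy at 3.51 ± 0.35, the death receptor family gene Eda2r at 3.68 ± 0.44 and Ptp4a3 at 1.54 ± 0.24. Mdm2, the p53 ubiquitin ligase, differed by 0.54 ± 0.18, and Cdkn1a, the p21 cell cycle inhibitor, by -0.21 ± 0.28 with overlapping groups. The set test gave a camera adjusted p of 0.000348 and adjusted p = 0.70 with an estimated correlation, while fry called this list, alone among the 35, at adjusted p = 0.005. Crosslink and excision repair genes did not pass as a set (camera adjusted p = 0.685, in the lower direction, with a median of -0.04, which was 0.08 when scaled by library size only, and a mean of 0.02). Of these 27 genes 0 passed over all genes or adjusted over the list alone, 2 were higher at an unadjusted p under 0.05, and DESeq2 called 1. Its lesion-bypass polymerase genes Rev1, Rev3l and Polh were at 0.68 ± 0.15, 0.78 ± 0.29 and -0.29 ± 0.17, and Brca2 was at 0.40 ± 0.19. The 24 NRF2 target and metallothionein genes had a median of 0.03 (camera adjusted p = 0.658). No member passed over all genes and 1 passed adjusted over the list alone, with 7 higher and 2 lower at an unadjusted p under 0.05 and 4 higher by DESeq2. Hmox1, which degrades haem, was at 17.8 and 19.8 CPM in vehicle and 71.6 and 73.5 CPM in cisplatin (1.95 ± 0.15), Fth1 was at 1.04 ± 0.26, Gstm1 at 1.11 ± 0.28 and Gsta3 at 2.45 ± 0.63. For 30 proliferation genes the median was 0.15 (camera adjusted p = 0.0873). The set passed with library size only (0.0372), with genes over 1 CPM in 2 libraries (0.0250), with exon plus intron reads (0.0109) and without vehicle library 2 (0.0195), and its test was in the lower direction without vehicle library 1 (0.910). None passed over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2, and Nusap1, Aurkb, Top2a and Kif11 had the smallest p, at 0.46 ± 0.18, 0.39 ± 0.20, 0.36 ± 0.19 and 0.38 ± 0.21.

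Chemokine genes were higher as a set, with a median log2 difference of 3.73 over 25 genes. Cxcl13 was the member that rose over all genes, 19 passed adjusted over the list alone, and 20 were higher at an unadjusted p under 0.05. The neutrophil attractant Cxcl1 was at 3.84 and 6.04 CPM in vehicle and at 42.6 and 89.1 CPM in cisplatin (3.73 ± 0.48), and Ccl6 differed by 5.67 ± 0.75. Cxcl3 had 2 reads over both vehicle libraries and 781 over both cisplatin libraries, a ratio of 342 with a counting interval of 94.5 to 2830. The camera adjusted p was 2.03e-09, and adjusted p = 0.70 with an estimated correlation. Other secretory factors of senescent cells had a median of 2.17 over 30 genes (camera adjusted p = 2.42e-07; adjusted p = 0.70 with an estimated correlation). Over all genes 0 of these passed and 17 passed adjusted over the list alone, with 20 higher at an unadjusted p under 0.05 and 20 by DESeq2. Gdf15, a stress-induced cytokine, was at 0.429 and 0.753 CPM in vehicle and at 16.6 and 17.8 CPM in cisplatin (4.85 ± 0.38), and the angiogenic factor Vegfa differed by 2.13 ± 0.26 and Csf3 by 3.26 ± 0.49. Feedback genes of the NF-kB pathway had a median of 1.25 over 20 genes (camera adjusted p = 6.76e-06; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes, 11 adjusted over the list alone, 13 higher at an unadjusted p under 0.05 and 11 by DESeq2. Bcl3 was at 2.54 ± 0.30, Tnfaip2 at 2.38 ± 0.42, Irak3 at 1.26 ± 0.24 and Nfkbiz at 1.74 ± 0.33. In these libraries the macrophage markers were higher by a median of 3.83.

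Complement genes were higher as a set, with a median of 3.44, and all 17 measured were higher in both cisplatin libraries than in both vehicle libraries. Over all genes 2 rose, among them C4b, and 17 passed adjusted over the list alone. C3, the central complement component, was at 5.27 and 10.3 CPM in vehicle and at 779 and 1153 CPM in cisplatin (6.95 ± 0.52, adjusted p = 0.0544), and Cfd, which is also the adipocyte gene adipsin, differed by 9.69 ± 0.96. The camera adjusted p was 2.93e-10, and adjusted p = 0.70 with an estimated correlation. Interferon-stimulated genes had a median of 1.93 over 29 genes (camera adjusted p = 6.64e-07; adjusted p = 0.70 with an estimated correlation). Over all genes 0 passed, against 1 adjusted over the list alone, 18 at an unadjusted p under 0.05 and 17 by DESeq2, all of these higher. Relative to the vehicle mean this list's median was 0.56 in cisplatin library 1 and 2.60 in library 2. Ifi27l2a was at 3.89 ± 0.46, the RNA sensor Ifih1 at 1.61 ± 0.36 and Gbp2 at 2.06 ± 0.51. The alternative macrophage activation list had a median of 2.74 over 16 genes (camera adjusted p = 5.16e-05; adjusted p = 0.70 with an estimated correlation). Chil3 rose over all genes and 6 passed adjusted over the list alone. The list median was 1.04 in cisplatin library 1 and 3.79 in library 2, against -0.64 and 0.64 in the vehicle libraries. The scavenger receptor Cd163 was at 3.48 ± 0.67, Clec10a at 3.69 ± 0.73 and the mannose receptor Mrc1 at 4.41 ± 1.03. MHC class II presentation genes had a median of 2.63 over 10 genes (camera adjusted p = 0.0121; adjusted p = 0.71 with an estimated correlation). By edgeR 0 passed over all genes or adjusted over the list alone, 1 was higher at an unadjusted p under 0.05, and DESeq2 called 7. Relative to the vehicle mean the median of this list was -0.35 and 0.35 in the vehicle libraries, 0.38 in cisplatin library 1 and 3.54 in library 2, and without cisplatin library 2 its camera adjusted p was 0.155. Cd74, the invariant chain, was at 27.6 and 45.2 CPM in vehicle and at 50.1 and 513 CPM in cisplatin (2.95 ± 1.12), with Ctss at 4.48 ± 0.90, H2-Aa at 2.94 ± 1.12 and H2-DMa at 2.22 ± 0.87. Macrophage and dendritic cell markers, with medians of 3.83 and 2.34, were higher in the same libraries.

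**Figure D3:**
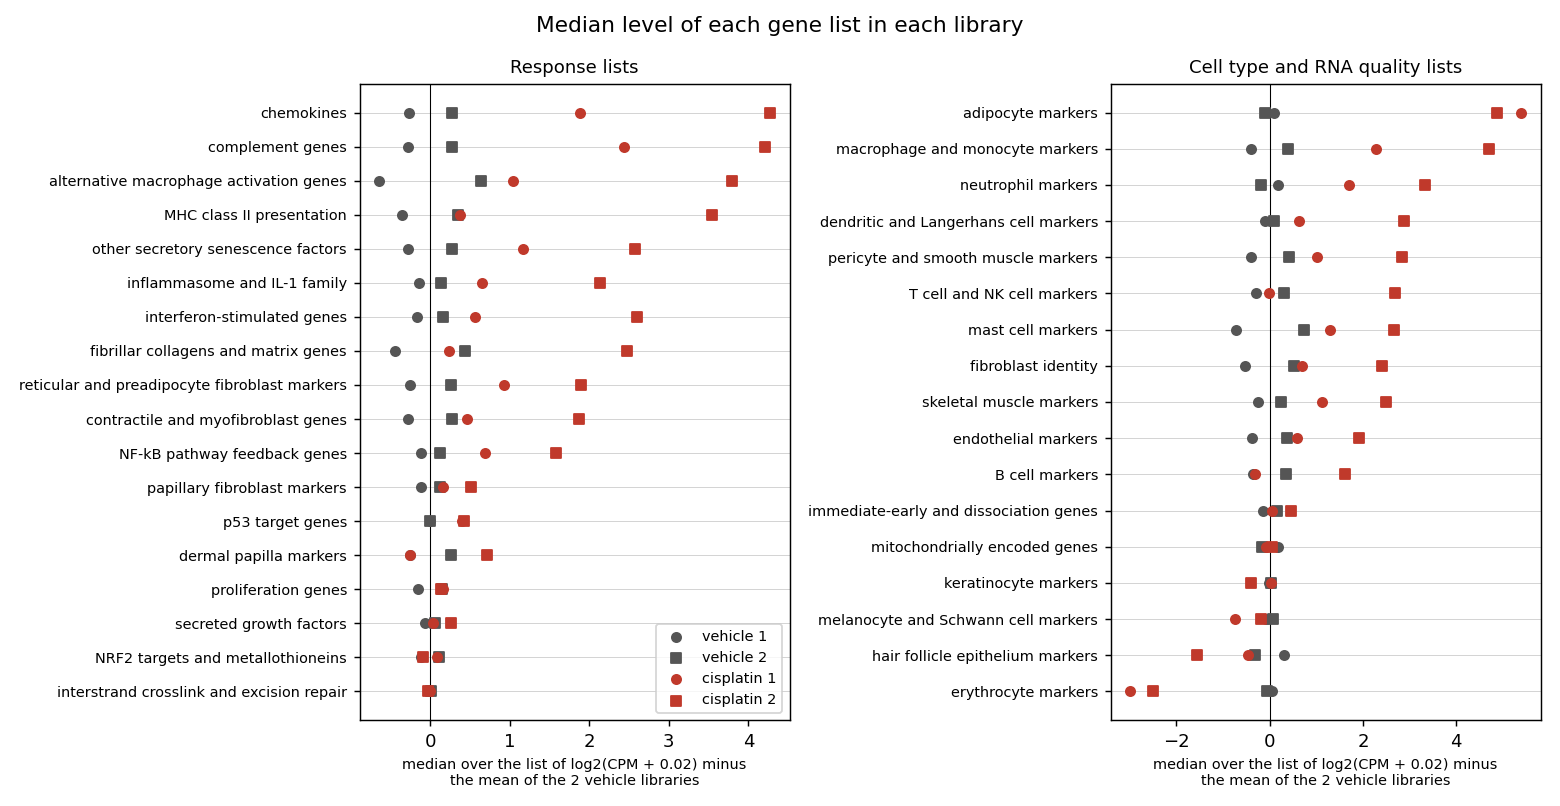
Median over each fixed gene list of log2(CPM + 0.02) in each library, relative to the mean of the 2 vehicle libraries, for response lists at the left and for cell type and RNA quality lists at the right. Circles are replicate 1 and squares replicate 2, with vehicle in grey and cisplatin in red. The macrophage list lies at 2.27 and 4.70 in the cisplatin libraries, the adipocyte list at 5.39 and 4.88 and the hair follicle list at -0.46 and -1.55.

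Matrix genes were higher as a set in cisplatin library 2, while their median in cisplatin library 1 lay between those of the vehicle libraries. The median over 36 genes was 1.60 (camera adjusted p = 6.77e-05; adjusted p = 0.71 with an estimated correlation), and relative to the vehicle mean it was -0.44 and 0.44 in the vehicle libraries, 0.23 in cisplatin library 1 and 2.47 in library 2; without cisplatin library 2 the camera adjusted p was 0.0832. The list took 0.328% and 0.839% of exon reads in vehicle and 0.596% and 3.30% in cisplatin. Fibroblast identity genes, with a median of 1.83, had medians of 0.70 and 2.42 in cisplatin libraries 1 and 2, and 7 of the matrix genes are also in another list. None passed over all genes or adjusted over the list alone, 15 were higher at an unadjusted p under 0.05, and DESeq2 called 15. Lox, which crosslinks collagen, was at 20.8 and 12.8 CPM in vehicle and 63.5 and 103 CPM in cisplatin (2.31 ± 0.37), Col5a3 was at 1.70 ± 0.42, Mfap5 at 3.20 ± 0.88 and Tnxb at 3.54 ± 1.01. Contractile and myofibroblast genes had a median of 1.34 over 20 genes (camera adjusted p = 0.00721; adjusted p = 0.71 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone. At an unadjusted p under 0.05, 7 were higher and 1 lower, and DESeq2 called 6 and 1. Without cisplatin library 2 the camera adjusted p of this list was 0.155. Pericyte and smooth muscle markers, with a median of 2.16, were higher in the same libraries, and 3 of the contractile genes are also in another list. Thbs1 was at 1.76 ± 0.22, Ccn1 at 1.56 ± 0.35 and Lmod1 at 2.57 ± 0.61, whereas the myofibroblast gene Lrrc15 was at -1.16 ± 0.33. Reticular and preadipocyte fibroblast markers had a median of 1.58 over 13 genes (camera adjusted p = 0.0033; adjusted p = 0.70 with an estimated correlation). Of the 13 none passed over all genes, 6 higher and 1 lower passed adjusted over the list alone, 8 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 7 higher. Gpx3 was at 6.95 and 14.5 CPM in vehicle and at 249 and 274 CPM in cisplatin (4.60 ± 0.43), the adipogenic regulator Pparg at 2.52 ± 0.34, Ebf1 at 1.75 ± 0.35 and Cd36 at 1.58 ± 0.34. Adipocyte markers were higher by a median of 5.43 in these libraries.

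Papillary fibroblast, dermal papilla and growth factor lists did not pass as sets. The 10 papillary markers had a median of 0.40 (camera adjusted p = 0.538), with Ntn1 at 1.22 ± 0.39, Dpp4 at -0.64 ± 0.20, Entpd1 at 1.87 ± 0.67 and Pdpn at 1.12 ± 0.48. None passed over all genes or adjusted over the list alone, 2 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher. The 20 dermal papilla markers had a median of 0.31 and a mean of 0.46 but a test in the lower direction (camera adjusted p = 0.825, and 0.0322 without cisplatin library 2). Corin was at 123 and 153 CPM in vehicle and at 84.7 and 40.0 CPM in cisplatin (-1.15 ± 0.39), Inhba at -0.80 ± 0.27 and Prom1 at 1.44 ± 0.51, with 0 passing over all genes or adjusted over the list alone, 2 higher and 3 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. Of 40 secreted growth factor genes (median 0.05, camera adjusted p = 0.678), 0 passed over all genes, and 5 higher and 1 lower passed adjusted over the list alone. Unadjusted p-values under 0.05 were found for 7 higher and 6 lower, and DESeq2 called 6 and 2. Igf1 was at 1.90 ± 0.35, the Wnt antagonist Dkk2 at 1.70 ± 0.29 and Fgf2 at 1.51 ± 0.27, with 13.2% of Fgf2 reads unique to it, while Nrg2 was at -1.22 ± 0.15.

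Markers of most non-epithelial cell types were higher after cisplatin. Adipocyte markers had a median of 5.43 over 18 genes, with 17 higher in both cisplatin libraries than in both vehicle libraries. Adipoq, Car3 and Plin4 rose over all genes, and 17 passed adjusted over the list alone (camera adjusted p = 7.74e-14; adjusted p = 0.70 with an estimated correlation). Macrophage and monocyte markers had a median of 3.83 over 26 genes, with 0 passing over all genes, 24 adjusted over the list alone, 24 higher at an unadjusted p under 0.05 and 24 by DESeq2 (camera adjusted p = 5.88e-09; adjusted p = 0.70 with an estimated correlation). Mpeg1 was at 2.58 and 3.49 CPM in vehicle and at 22.8 and 115 CPM in cisplatin (4.51 ± 0.88), and Mertk at 0.98 ± 0.14. Neutrophil markers had a median of 2.80 over 17 genes, with 0 passing over all genes, 10 adjusted over the list alone, 12 higher at an unadjusted p under 0.05 and 10 by DESeq2 (camera adjusted p = 6.76e-06; adjusted p = 0.70 with an estimated correlation). Of the 17 neutrophil markers 4 exceeded 1 CPM in both vehicle libraries. With genes over 1 CPM in 2 libraries 9 were left, and the camera adjusted p was 0.000214. Clec4d was at 6.14 ± 1.31. Elane had 2 reads over both vehicle libraries and 82 over both cisplatin libraries, a ratio of 36 with a counting interval of 9.64 to 302. Mast cell markers had a median of 1.91 over 11 genes, with 0 passing over all genes, 4 adjusted over the list alone, 6 higher at an unadjusted p under 0.05 and 6 by DESeq2 (camera adjusted p = 0.000244; adjusted p = 0.70 with an estimated correlation). Tpsab1 was at 4.16 ± 0.71, Fcer1a at 2.64 ± 0.71 and Hdc at 2.80 ± 0.74. Dendritic and Langerhans cell markers had a median of 2.34 over 12 genes (camera adjusted p = 0.0106; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone and 6 higher both at an unadjusted p under 0.05 and by DESeq2. With genes over 1 CPM in 2 libraries 5 were left and the camera adjusted p was 0.298, and relative to the vehicle mean the list median was 0.63 in cisplatin library 1 and 2.88 in library 2. Irf8 was at 2.60 ± 0.67 with 49.6% of its reads unique to it, Clec9a at 2.08 ± 0.62 and Itgax at 3.46 ± 1.06. T and NK cell markers had a median of 2.07 over 17 genes (camera adjusted p = 0.0106, and adjusted p = 0.73 with an estimated correlation). Of these 17 markers 2 exceeded 1 CPM in both vehicle libraries. None passed over all genes or adjusted over the list alone, 1 was higher at an unadjusted p under 0.05, and DESeq2 called 2. Il7r was at 3.13 ± 0.95, Cd3e at 2.30 ± 0.90 and Cd4 at 3.17 ± 1.24, and relative to the vehicle mean the list median was -0.30 and 0.30 in the vehicle libraries, -0.01 in cisplatin library 1 and 2.68 in library 2; without cisplatin library 2 the test was in the lower direction (camera adjusted p = 0.877). The 7 B cell markers did not pass as a set (median 1.15, camera adjusted p = 0.526, and 0.0104 without cisplatin library 1), with 0 passing over all genes, adjusted over the list alone or by DESeq2 and 1 higher at an unadjusted p under 0.05. Pax5 was at 1.82 ± 0.64, Cd79a at 1.48 ± 0.64 and Blnk at -0.46 ± 0.19.

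Fibroblast identity genes were also higher as a set, with a median of 1.83 over 16 genes (camera adjusted p = 0.000244, and adjusted p = 0.70 with an estimated correlation). Relative to the vehicle mean their median was -0.52 and 0.52 in the vehicle libraries, 0.70 in cisplatin library 1 and 2.42 in library 2. Of these genes 9 were higher in both cisplatin libraries than in both vehicle libraries. Of the 16 none passed over all genes, 2 passed adjusted over the list alone, and 8 were higher at an unadjusted p under 0.05 and by DESeq2. Pdgfra, a receptor that marks fibroblasts, was at 18.8 and 25.8 CPM in vehicle and at 58.8 and 110 CPM in cisplatin (1.92 ± 0.37), Twist1 at 1.96 ± 0.36 and Dpt at 3.82 ± 0.93. Endothelial markers had a median of 1.30 over 16 genes (camera adjusted p = 0.000273; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone and 7 higher both at an unadjusted p under 0.05 and by DESeq2. Relative to the vehicle mean the endothelial median was 0.59 in cisplatin library 1 and 1.92 in library 2. Cldn5 was at 1.04 ± 0.33, Esam at 1.49 ± 0.48 and Emcn at 1.48 ± 0.48. Pericyte and smooth muscle markers had a median of 2.16 over 12 genes (camera adjusted p = 0.000136; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes, 1 adjusted over the list alone, 10 higher at an unadjusted p under 0.05 and 9 by DESeq2. The pericyte median was 1.02 in cisplatin library 1 and 2.83 in library 2. Mcam was at 2.03 ± 0.29, Kcnj8 at 2.82 ± 0.65 and Abcc9 at 2.95 ± 0.81. Skeletal muscle markers had a median of 1.83 over 16 genes (camera adjusted p = 3.51e-05; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes, 6 adjusted over the list alone, 9 higher at an unadjusted p under 0.05 and 8 by DESeq2. Acta1 was at 3.32 ± 0.77 and Tnnt3 at 2.54 ± 0.62, and Mb, at 3.14 ± 0.59, overlaps Apol6 on the other strand, so that their reads cannot be told apart without strand.

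Hair follicle epithelium markers were lower as a set and abundant in every library. They took 4.75% and 3.44% of exon reads in the vehicle libraries and 2.997% and 1.43% in the cisplatin libraries, with a median log2 difference of -0.88 over 19 genes (camera adjusted p = 3.71e-06; adjusted p = 0.70 with an estimated correlation). None passed over all genes or adjusted over the list alone, 8 were lower at an unadjusted p under 0.05, and DESeq2 called 7. The hair keratin gene Krt31 was at 3236 and 2170 CPM in vehicle and at 1198 and 811 CPM in cisplatin (-1.43 ± 0.35), Krt33a at -1.61 ± 0.40 and Krt33b at -1.26 ± 0.30. Fibroblast identity genes took 0.181% and 0.546% of exon reads in vehicle and 0.315% and 2.22% in cisplatin. Keratinocyte markers did not pass as a set (camera adjusted p = 0.581, in the lower direction), with a median of -0.16 and a mean of 0.39 over 24 genes. Of the 24 none passed over all genes, 1 passed adjusted over the list alone, 5 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 3 in each direction. Krt14, a basal keratin, was at -1.001 ± 0.24, and Krt6b and Krt16, keratins of wounded epidermis, were at 5.47 ± 0.59 and 2.47 ± 0.58. Melanocyte and Schwann cell markers were lower as a set (median -0.44 over 15 genes, camera adjusted p = 0.0272; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes, 1 adjusted over the list alone, 5 lower at an unadjusted p under 0.05 and 4 by DESeq2. The camera adjusted p of this list was 0.0593 without vehicle library 2, 0.746 without cisplatin library 1 and 0.0571 with exon plus intron reads. The pigment genes Mlana, Dct and Pmel were at -1.02 ± 0.18, -1.01 ± 0.30 and -1.06 ± 0.32. Erythrocyte markers were lower as a set as well (median -3.04 over 8 genes, camera adjusted p = 3.58e-05; adjusted p = 0.70 with an estimated correlation), with 0 passing over all genes, 1 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 by DESeq2. The globin gene Hba-a1, with 50.8% of its reads unique to it, was at 461 and 403 CPM in vehicle and at 3.05 and 38.2 CPM in cisplatin (-4.39 ± 1.24).

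RNA quality lists did not pass as sets. Immediate-early and dissociation genes had a median of 0.30 over 24 genes (camera adjusted p = 0.538), with 0 passing over all genes or adjusted over the list alone, 3 higher and 4 lower at an unadjusted p under 0.05 and 3 in each direction by DESeq2. Ier3 was at 1.65 ± 0.37, Zfp36 at 1.53 ± 0.34 and the heat shock gene Hspa1b at -0.996 ± 0.20, with 75.5% of its reads unique to it. The 13 mitochondrially encoded genes had a median of -0.09 (camera adjusted p = 0.526), which was 0.05 when scaled by library size only, and took between 3.05% and 3.89% of exon reads per library. None passed over all genes, adjusted over the list alone or by DESeq2, and 1 was lower at an unadjusted p under 0.05. Here mt-Nd4l was at -0.60 ± 0.18, mt-Nd6 at 0.23 ± 0.18 and mt-Co2 at -0.47 ± 0.37.

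The authors' deposited table of cisplatin against vehicle called 2675 genes higher and 1113 lower at its own false discovery rate of 0.05. All 14 genes that rose by edgeR's quasi-likelihood test were among the 2675 of the authors' deposited table, and 0 of its 1113 lower genes passed that test, which called 0 lower genes. In the authors' deposited table Il1b had a log2 fold change of 4.43 and Nlrp3 one of 4.47, each with a false discovery rate printed as 0. Of its calls 3702 were tested here, and all 3702 had the same direction in both. The authors' deposited table compares the same groups of the same study, so neither shared directions nor correlated values are independent support. Across 17054 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those computed here had a Pearson r of 0.994 and a Spearman rho of 0.995.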

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

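Intron reads are not among the exon counts that gave the values per gene in the report, and they were higher in both cisplatin libraries than in both vehicle libraries for 4 of the 6 genes that were always named; the tests of explanations in this part were all chosen after the result was seen. Il1b had 0.055 and 0.14 intron reads per 1000000 gene reads in vehicle, and 0.992 and 7.25 in cisplatin. Nlrp3 had 0.116 and 0.14 in vehicle against 1.176 and 8.09 in cisplatin. Casp1 had 1.30 and 1.12 in vehicle against 1.972 and 2.11, and Mdm2 had 17.4 and 14.1 against 19.871 and 23.1. These values were scaled by gene reads alone and were not tested.

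Il1b was higher in both cisplatin libraries, by 5.18 ± 1.24 on the log2 scale, without passing the test. An unchanged cell mixture with induction in fibroblasts as the whole cause is argued against by the macrophage markers. Their median was 3.83, with 24 of 26 higher in both cisplatin libraries. A mere loss of epithelial cells is argued against by the macrophage median, which exceeded the endothelial one by 2.53 (95% bootstrap interval over genes 2.17 to 2.88). That interval leaves out the spread between libraries. Relative to the vehicle mean, cisplatin libraries 1 and 2 had macrophage medians of 2.27 and 4.70 and endothelial medians of 0.59 and 1.92. More macrophage and neutrophil RNA stays open as a source of the Il1b reads. Between groups Il1b exceeded 90.7% of 43 such markers, within their range of -0.27 to 6.14. The top value was that of the neutrophil marker Clec4d, with 20 reads over both vehicle libraries. The highest macrophage marker was at 5.02, below Il1b at 5.18. Between the cisplatin libraries Il1b exceeded 93.0% of the 43 markers and differed by 3.29 against a marker median of 2.37. A gene so high among the markers neither shows nor excludes that source. Of the 26 macrophage markers 4 are in another list and 15 exceeded 1 CPM in both vehicle libraries, and the most abundant, Apoe, was at -0.27 ± 0.28, while Lyz2 went from 8.81 and 17.2 CPM to 85.8 and 445 CPM; the labels name no sort. Induction of Il1b by cisplatin in fibroblasts or in immune cells, on top of a changed mixture, stays open and was not tested, since these libraries do not separate cells.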

How the results depend on the processing

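Exon plus intron reads, edgeR's legacy quasi-likelihood method and removal of the length trend were chosen after seeing the data, the other settings before. The 14 higher genes became 4 with upper quartile factors, 4 with library size only, 26 without the low-count filter, 1744 with DESeq2 (662 genes with no adjusted p), 1587 with the likelihood ratio test, 145 at an adjusted p of 0.1, 0 with limma-voom and 0 with the legacy method, whose smallest adjusted p was 0.0504; leaving out a library gave 0 to 3304. Other settings gave 10 to 21. The 0 lower genes became 394 with DESeq2, 267 with the likelihood ratio test and 4 at an adjusted p of 0.1, and leaving out a library gave 0 to 973. With a replicate block 1568 genes were higher and 560 lower (3550 and 2507 at an unadjusted p under 0.05), and Il1b was at 4.51 (adjusted p = 0.0448); deviations of same-numbered libraries correlated at 0.398, but 2 pairs cannot show pairing. The block ended the call of melanocyte and Schwann cell markers (adjusted p = 0.052). All 14 genes were also called with DESeq2, the likelihood ratio test, the block and without either cisplatin library. Il1b passed at 5.18 with DESeq2 and 5.19 with the likelihood ratio test, and ranged from 2.75 to 6.03 over the fits without 1 library, in which a lone library is assumed to vary like the other group; over all settings its adjusted p ranged from 6.28e-07 to 0.947. The 22 higher lists became 0 with an estimated correlation and 1 with fry, and the 3 lower lists 0 with each, whereas other settings gave 18 to 23 and 2 to 4. The causes of these shifts were not tested.

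Of 141 named genes besides Il1b 2 reversed: Cdkn1a ranged from -0.50 to 0.14 over the fits without 1 library, the higher value without vehicle library 1, and mt-Nd4l was at 0.13 with the length trend removed. Lists whose test reversed are given with their mean log2 difference minus that of other genes. This mean does not depend on the list test, and its sign can differ from that of the test. Fry turned crosslink repair (-0.255), dermal papilla (0.066) and keratinocytes (0.068) to the higher direction. Library size only turned crosslink repair (-0.252) to higher and growth factors (0.082) to lower. Exon plus intron reads turned crosslink repair (-0.128) and dermal papilla (0.101) to higher, and the block turned dermal papilla (0.066) to higher. Over the fits without 1 library, dermal papilla ranged from -0.271 to 0.373, proliferation from -0.224 to -0.016, NRF2 targets from -0.198 to 0.160, T and NK cells from -0.095 to 2.471, B cells from -0.313 to 1.349, keratinocytes from -0.166 to 0.271, immediate-early genes from -0.173 to 0.111 and mitochondrial genes from -0.565 to -0.241. Of these lists T and NK cells alone had passed, and they reversed without cisplatin library 2. The causes were not tested. Depth limits genes near 3 reads, 0.0201 to 0.0253 CPM, such as Cxcl3 and Elane.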

Other observations

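The gene groups and tests in this part were all chosen after the values were seen. Cytosolic ribosomal protein genes were lower after cisplatin, with a median log2 difference of -0.73 over 83 genes, of which 81 were below 0; the median was -0.61 with library size only and -0.74 with RLE and upper quartile factors. Major urinary protein genes, 22 in the files, summed to 7.15 and 3.42 CPM in vehicle and to 353 and 383 CPM in cisplatin, with 18.5% of their reads unique to a gene. The 4 adult globin genes summed to 829 and 751 CPM in vehicle and to 3.53 and 67.6 CPM in cisplatin.

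Adipocyte genes were far higher in both cisplatin libraries, led by Cfd, at 1.99 and 0.791 CPM in vehicle and 1710 and 573 CPM in cisplatin. A mere loss of epithelial cells is argued against by the adipocyte median, which exceeded the fibroblast identity median by 3.61 (95% bootstrap interval over genes 1.16 to 6.72). That interval leaves out the spread between libraries. Relative to the vehicle mean, cisplatin libraries 1 and 2 had adipocyte medians of 5.39 and 4.88 and fibroblast medians of 0.70 and 2.42. Liver RNA as the source of Mup22 is argued against by albumin, which reached 2.03 CPM where Mup22 was at 227 CPM or more. Adipocyte RNA in the cisplatin libraries with next to none in vehicle stays open, since 17 of 18 markers being higher in both cisplatin libraries is the pattern itself and decides nothing. Of the 18 markers 3 are in another list and 10 exceeded 1 CPM in both vehicle libraries, among them Fabp4, at 558 and 435 CPM in vehicle and 792 and 730 CPM in cisplatin. An effect of cisplatin on the skin or on the fibroblasts themselves likewise stays open and was not tested.

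Ribosomal protein genes have short transcripts, and shorter genes had lower log2 differences, with a median of -0.294 in the shortest of 10 length classes and 0.155 in the longest. A trend on exon length as the whole cause is argued against by the ribosomal median. It was -0.47 after that trend was removed, with 81 of 83 genes still below 0. The exon length used is that of the gene and not of its transcripts, so a bias against short transcripts stays open. A lower share of hair follicle epithelium cannot be told apart from other causes, because 4 libraries are too few: between cisplatin libraries 1 and 2 the ribosomal and hair follicle medians differed by -0.48 and -0.84, and between vehicle libraries by -0.30 and -0.63. An effect of cisplatin on ribosomal protein genes stays open and was not tested.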
